A study of Mus musculus with 30 samples.

How the data were processed

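The data were RNA-seq libraries of mouse bone-marrow-derived macrophages of 3 genotypes in 5 conditions, with 2 libraries in each of the 15 groups. Per the labels' protocols, libraries were made from total RNA with a stranded kit that depletes ribosomal RNA and were read as single ends on a NextSeq instrument. The submitters' processing notes name kallisto, edgeR and limma without versions, and they name the build GRCh38, a human build, although the organism and the gene symbols are mouse. The kallisto index, the annotation, the strand setting and the step from transcripts to genes are not given in the sources used here.

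The table of estimated counts deposited by the authors holds 32006 genes by symbol. The values are not whole, with 1.06% of those above 0 within 0.001 of a whole number, so they are not plain counts of reads. How the fractions arose is not given. Estimated counts can share reads between near-identical genes, and members of gene families and pseudogenes are uncertain for that reason. The authors also deposited a log2 table of counts per 1000000 (CPM) for 12879 genes. These are the genes with at least 1 CPM in at least 2 libraries, with 0 exceptions, and in each library the log2 values equal log2 of the estimated count plus 0.5 minus a constant (largest SD over genes 5.2e-15). It was used only as an alternative. No column of another sample was present (0), and 0 lines of the count table named no gene. Symbols were matched to GENCODE M21 on GRCm38 for coordinates. Of the 32006 symbols 31889 matched once, as did 12845 of those in the log2 table (99.7%). As the authors' build is in doubt, these coordinates belong to GRCm38 alone.

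Groups came from the labels, which give genotype, agonist, time and a replicate number. Estimated counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, robust fit, R 4.3.3) after TMM normalization and filterByExpr by group, which kept 14968 genes. All 30 libraries entered 1 fit of 15 groups, which left 15 residual degrees of freedom, and the common biological coefficient of variation was 0.089. Adjusted p-values are Benjamini-Hochberg values over the genes of a comparison, a gene was called at an adjusted p under 0.05, and the SE is the size of the log2 fold change over the square root of the F statistic. Comparisons were Ripk3Casp8KO against Ripk3KO and Ripk3KO against WT in each condition and averaged over the 4 stimulated conditions, each stimulated condition against untreated in WT, LPS against CpG in WT at each time, and the differences between these changes as interactions. The untreated libraries are labelled 6 h and served as the baseline of both times. A log2 fold change fitted for a gene with at most 3 counts over a group is not given as a fold. Such genes are given as levels, or against a floor of 3 counts over the group where the group had none.

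There were 27 gene lists. They covered cytokines, the IL-12 family, chemokines, NF-kB feedback, interferon-stimulated, immediate early, inflammasome, cell death, TLR signalling, sterol synthesis, glycolysis and hypoxia, cell cycle, antigen presentation, NRF2, unfolded protein and amino acid response, and lysosome genes. Markers were those of macrophages, neutrophils, dendritic cells, lymphocytes, fibroblasts, mast cells and basophils, osteoclasts and erythroid cells, with sex-linked, dissociation stress and mitochondrially encoded genes as checks. Lists were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 27 lists of a comparison, and again with an estimated correlation and with fry (limma 3.58.1). All 5 IL-12 family genes are also in the cytokine list.

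Named genes followed a rule. A set of 12 was always named: Casp8, Ripk3, Il12b, Il12a, Il23a, Il6, Il1b, Tnf, Il10, Rel, Ifnb1 and Cxcl10. For each genotype comparison the 8 largest rises and the 8 largest falls qualified among called genes with at least 5 CPM in the higher group and no overlap between replicates (for the averaged comparisons, the same direction in all 4 conditions). For the response in WT the 5 largest each way qualified by the same filter, and for agonist and interaction comparisons 5 each way without the overlap condition. For each list up to 4 called members with the largest change qualified, or up to 2 with the smallest p where none was called. Predicted genes were skipped. The text gives a selection of these. The comparisons, alternatives, lists and this rule were fixed before the data were examined, with some exceptions. Chosen later were 2 alternatives that are named in the closing section and the comparison of Ripk3Casp8KO with WT. So were the tests of the Ripk3 change at CpG 6 h against the other conditions and of LPS contaminating the CpG. The comparison of Ripk3Casp8KO with WT was run under no alternative but the estimated correlation and fry in its set tests.

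The alternatives were size factors by the RLE method, library size alone, no expression filter, the genes of the authors' log2 table, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the libraries of the compared groups, each library left out in turn with the spread pooled over the groups, exclusion of 280 tested genes within 10 Mb of Casp8 or Ripk3, and limma on the authors' log2 table. The edgeR, limma-voom and DESeq2 tests were checked on simulated data, and the other alternatives were not. With the means and depths of Ripk3Casp8KO against Ripk3KO after LPS for 6 h and 14968 genes, edgeR called 65.7% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 12 calls among 14768 unchanged genes. Changes under 2-fold can therefore be missed at this depth. Replicates were checked for repeated libraries by a chi-square of their counts. The mean per gene ranged from 5.5 to 33.41 over the 15 pairs, so no pair differed by less than the sampling noise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.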

Results

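Total RNA depleted of ribosomal RNA was sequenced from mouse bone-marrow-derived macrophages, which are marrow precursors grown into macrophages in medium conditioned by L929 cells. The cells had 3 genotypes: wild type (WT), loss of the necroptosis kinase gene Ripk3 (Ripk3KO), and loss of both Ripk3 and Casp8, the gene of the cell death protease caspase-8 (Ripk3Casp8KO). Mice that lack Casp8 are viable on a Ripk3-null background, so Ripk3KO was the control for Casp8 loss. The title of the series names caspase-8, cytokine expression that depends on the NF-kB subunit c-Rel, and resistance to the parasite Toxoplasma. Each genotype was left untreated (labelled 6 h) or stimulated with lipopolysaccharide (LPS, 100 ng/mL, a ligand of TLR4) or CpG DNA (1 uM, a ligand of TLR9) for 2 h or 6 h. This gave 15 groups of 2 libraries, 30 in all. Estimated counts summed to 20.42 to 64.09 M per library, where M stands for 1000000 counts, with a median of 29.3 M. The WT untreated libraries were the deepest at 56.14 and 64.09 M, and the others reached at most 35.54 M. The labels call the libraries of a group biological replicates without giving separate mice or cultures, so the p-values measure the spread between these samples, which may be technical. Levels are counts per 1000000 counts of the scaled library (CPM), given as mean ± SD with n = 2 libraries, changes are log2 fold changes with their standard error (SE), and floors cover counting error only. In the genotype comparisons within a condition, both libraries of one group lay beyond both of the other for each gene given as changed. Set test calls held with an estimated correlation between genes unless a second adjusted p is given.

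Casp8 (chromosome 1, 58795374 to 58847503, plus strand, GRCm38 in the GENCODE M21 annotation) was lower in every Ripk3Casp8KO library. In untreated cells its level was 16.5 ± 0.215 CPM in Ripk3Casp8KO, 84.7 ± 1.12 in Ripk3KO and 87.1 ± 2.27 in WT (n = 2 each), a log2 fold change between the knockouts of -2.36 (SE 0.07, adjusted p = 3.85e-15). With LPS for 6 h Casp8 reached 275 ± 5.51 CPM in WT and 291 ± 2.68 in Ripk3KO and stood at 50.5 ± 0.157 in Ripk3Casp8KO, a change of -2.53 (SE 0.06, adjusted p = 5.71e-16). The changes in the libraries labelled LPS 2 h, CpG 2 h and CpG 6 h were -2.59, -2.28 and -2.41 (SE 0.07 each, adjusted p = 2.38e-15, 1.87e-14 and 4.3e-15). The levels went from 62.5 ± 4.62 to 10.4 ± 0.805, from 61.1 ± 2.69 to 12.6 ± 0.655 and from 78.4 ± 5.26 to 14.7 ± 0.549 CPM. WT stood at 71.7 ± 0.74, 70.1 ± 0.546 and 86.6 ± 3.7. Gene-level counts cannot show which exons were removed, so the remaining counts do not measure intact transcript.

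Ripk3 (chromosome 14, 55784995 to 55788865, minus strand, GRCm38) was lower in Ripk3KO than in WT in 4 of the 5 conditions. Untreated cells had 19 ± 0.247 CPM in WT, 6.25 ± 0.193 in Ripk3KO and 5.59 ± 0.414 in Ripk3Casp8KO, a change from WT to Ripk3KO of -1.60 (SE 0.11, adjusted p = 1.23e-08). The libraries labelled LPS 2 h went from 15.4 ± 0.226 to 7.72 ± 1.18 CPM, and those labelled CpG 2 h from 15.7 ± 0.703 to 7.69 ± 0.98. Those of LPS 6 h went from 9.33 ± 0.71 to 4.74 ± 0.205. Ripk3Casp8KO stood at 5.56 ± 0.5, 5.64 ± 0.129 and 4.37 ± 0.16 in these conditions. These changes were -1.0 (SE 0.11, adjusted p = 4.32e-06), -1.04 (SE 0.11, adjusted p = 2.8e-06) and -0.98 (SE 0.12, adjusted p = 3.53e-05). The last was not called with only the libraries of the compared groups (-0.97). At CpG 6 h the 3 genotypes had similar levels, 11 ± 0.491 CPM in WT, 9.52 ± 1.01 in Ripk3KO and 11.3 ± 0.125 in Ripk3Casp8KO, and the change from WT to Ripk3KO was -0.20 (SE 0.11, adjusted p = 0.377). A test of the difference between that change and the mean of the other 4, chosen after that change was seen and not run under the alternatives, gave 0.95 (SE 0.13, adjusted p = 0.00108). The Ripk3 transcript therefore did not mark the knockout libraries at CpG 6 h, while Casp8 was lower in those labelled Ripk3Casp8KO. Genotype names at CpG 6 h follow the labels throughout, and these are the libraries labelled Ripk3KO and Ripk3Casp8KO at CpG 6 h.

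**Figure D1:**
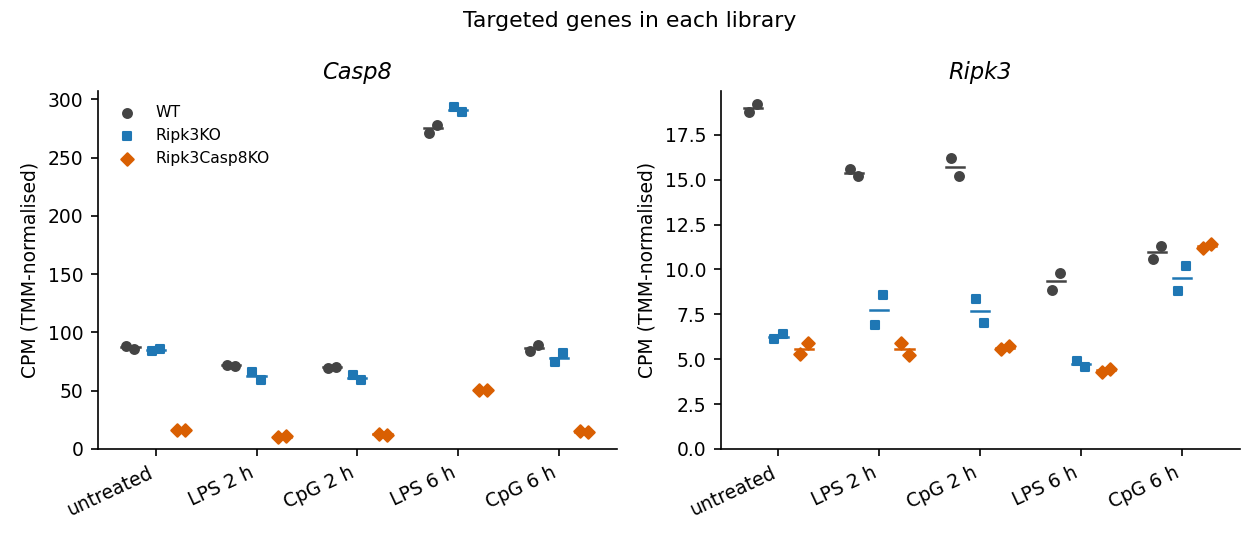
Levels of Casp8 and Ripk3 in CPM on linear axes from 0, by condition and genotype, with a point for each library and a line for each group mean. Casp8 stays at or below 50.5 CPM on average in every Ripk3Casp8KO group, and the 3 genotypes of the Ripk3 panel come together at CpG 6 h.

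Stimulation of WT macrophages raised NF-kB feedback genes, cytokines and chemokines in all 4 stimulated conditions. All 27 NF-kB feedback and target genes rose over all genes in each condition, as they did adjusted over the list alone, with median log2 fold changes of 3.97, 3.93, 4.74 and 3.53 for the libraries labelled LPS 2 h, CpG 2 h, LPS 6 h and CpG 6 h (camera adjusted p = 5.24e-209, 2.81e-164, 9.48e-79 and 7.88e-110). Tnf, an early inflammatory cytokine, went from 36.2 ± 0.357 CPM to 2140 ± 20.4, 2520 ± 23.3, 5320 ± 26.7 and 2950 ± 25.5, changes of 5.88, 6.12, 7.20 and 6.35 (SE 0.06 each, adjusted p at most 5.56e-24). Il12b, which encodes the p40 subunit of IL-12 and IL-23 (chromosome 11, 44400063 to 44414033), went from 0.0212 ± 0.03 CPM to 217 ± 1.9, 609 ± 3.11, 1800 ± 66.5 and 812 ± 22.2. Nos2, the inducible nitric oxide synthase, went from 0.0273 ± 0.0213 to 36.4 ± 5.06, 58.2 ± 3.62, 2730 ± 138 and 107 ± 18.7. Csf2, the gene of GM-CSF, had no counts in untreated WT and was at least 531-fold higher in the libraries labelled LPS 2 h and at least 437-fold higher in those labelled CpG 2 h, against a floor of 3 counts over the group. Of 27 cytokines, 20, 25, 25 and 25 rose and 1 fell in each condition (adjusted over the list alone, 21, 25, 25 and 26 rose, camera adjusted p = 3.47e-42, 9.31e-57, 1.86e-39 and 7.43e-41). Of 22 chemokines 18, 20, 19 and 20 rose and 0, 0, 1 and 1 fell (adjusted over the list alone, 19, 20, 19 and 20 rose, camera adjusted p = 1.67e-58, 1.77e-79, 9.72e-45 and 1.4e-55). The median changes of the cytokines were 4.50, 6.70, 7.73 and 5.29 as fitted, and 3.52, 6.12, 7.62 and 4.38 with members near 0 counts set to their bound.

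Cell cycle genes fell with stimulation of WT cells, 22 and 24 of 30 in the libraries labelled LPS 2 h and CpG 2 h and all 30 after either agonist at 6 h, with medians of -0.52, -0.62, -2.62 and -1.12 (adjusted over the list alone, 23, 24, 30 and 30, camera adjusted p = 7.32e-06, 1.84e-06, 6.48e-25 and 5.24e-23). Sterol synthesis genes fell after LPS at 6 h, 20 of 24 against 2 that rose, the same counts as adjusted over the list alone (camera adjusted p = 0.000145). Sqle, a sterol synthesis enzyme, changed by -2.87 there (SE 0.07, adjusted p = 9.96e-19). Slc7a11, the cystine transporter among the NRF2 targets, rose by 5.46 after CpG at 6 h (SE 0.12, adjusted p = 1.03e-18), where 11 of 14 NRF2 targets rose and 1 fell, also adjusted over the list alone (camera adjusted p = 9.07e-07). Casp8 itself rose after LPS at 6 h by 1.66 (SE 0.06, adjusted p = 7.14e-16). Rel, which encodes c-Rel, rose in all 4 conditions by 2.71, 3.17, 2.72 and 1.79 (SE 0.16 each, adjusted p at most 5.64e-09). The genes called numbered 5986 (3108 higher), 7125 (3646 higher), 10007 (4942 higher) and 8084 (4068 higher). With library size as the only scaling the share of higher calls went from 51.9% to 24.7%, from 51.2% to 21.7%, from 49.4% to 19.8% and from 50.3% to 27.5%. The median of all genes went from -0.03, -0.02, 0 and -0.01 to -0.25, -0.35, -0.80 and -0.30, so directions are relative to the bulk of genes. TMM factors moved mostly with condition, from 1.222 to 1.271 untreated and from 0.696 to 0.727 after LPS at 6 h. After LPS at 6 h those of Ripk3KO, 0.698 and 0.696, lay below those of WT, 0.727 and 0.721, and of Ripk3Casp8KO, 0.717 and 0.719.

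The agonists differed in interferon-stimulated genes, in opposite directions at the 2 times. At 6 h all 50 of these genes were higher after LPS than after CpG in WT, over all genes and adjusted over the list alone, by a median of 3.19 (camera adjusted p = 1.43e-140). Cxcl10, an interferon-induced chemokine, stood at 7400 ± 87.3 against 172 ± 1.47 CPM, a difference of 5.43 (SE 0.09, adjusted p = 2.46e-20). Iigp1, an interferon-induced GTPase, was at 881 ± 18.3 against 8.31 ± 1.25 (6.72, SE 0.13, adjusted p = 3.29e-19). In the libraries labelled 2 h the order was turned, with 49 of 50 lower in those labelled LPS than in those labelled CpG, over all genes and adjusted over the list alone, by a median of -1.94 (adjusted p = 1.45e-08 with an estimated correlation). Ifnb1, the gene of interferon beta (chromosome 4, 88522025 to 88522774), was at 0.0428 ± 0.0212 CPM in the libraries labelled LPS 2 h, 3 counts over the group, and at 47.3 ± 4.51 in those labelled CpG 2 h. Rsad2, an antiviral enzyme, was at 38.9 ± 3.74 against 2560 ± 271 CPM (-6.04, SE 0.14, adjusted p = 3.59e-17). Cxcl10 was at 73.9 ± 3.36 against 2860 ± 285 (-5.27, SE 0.09, adjusted p = 1.29e-19). As background, TLR4 signals to Ifnb1 through the adaptor TRIF and TLR9 does not use TRIF. The labels of the 2 h libraries are in doubt, and they are called the libraries labelled LPS 2 h or CpG 2 h.

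Other groups also separated the agonists. At 6 h in WT, 19 of 27 cytokines were higher after LPS and 1 was lower (adjusted over the list alone, 19 and 2, camera adjusted p = 6.8e-18), among them Il10, the anti-inflammatory cytokine, at 108 ± 1.74 against 4.55 ± 0.0632 CPM (4.57, SE 0.11, adjusted p = 4.52e-18). Of 24 sterol genes 22 were lower after LPS, over all genes and adjusted over the list alone (median -1.15, camera adjusted p = 2.35e-12), as were 12 of 14 NRF2 targets by either adjustment (median -1.54, camera adjusted p = 6.4e-08). In the libraries labelled 2 h, 18 of 27 cytokines were lower in those labelled LPS and 1 was higher (adjusted over the list alone, 24 and 1, camera adjusted p = 4.22e-41), with Il6 at 3.49 ± 0.0618 against 66.4 ± 9.5 CPM (-4.25, SE 0.14, adjusted p = 8.25e-14). The tests called 1993 genes at 2 h (769 higher) and 7653 at 6 h (3710 higher). Under library size alone the share of higher calls went from 38.6% to 68.6% and from 48.5% to 18.7%. The median of all genes went from 0.01 to 0.12 and from -0.01 to -0.52. Without the first WT library labelled LPS 2 h the 2 h count was 1229.

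**Figure D2:**
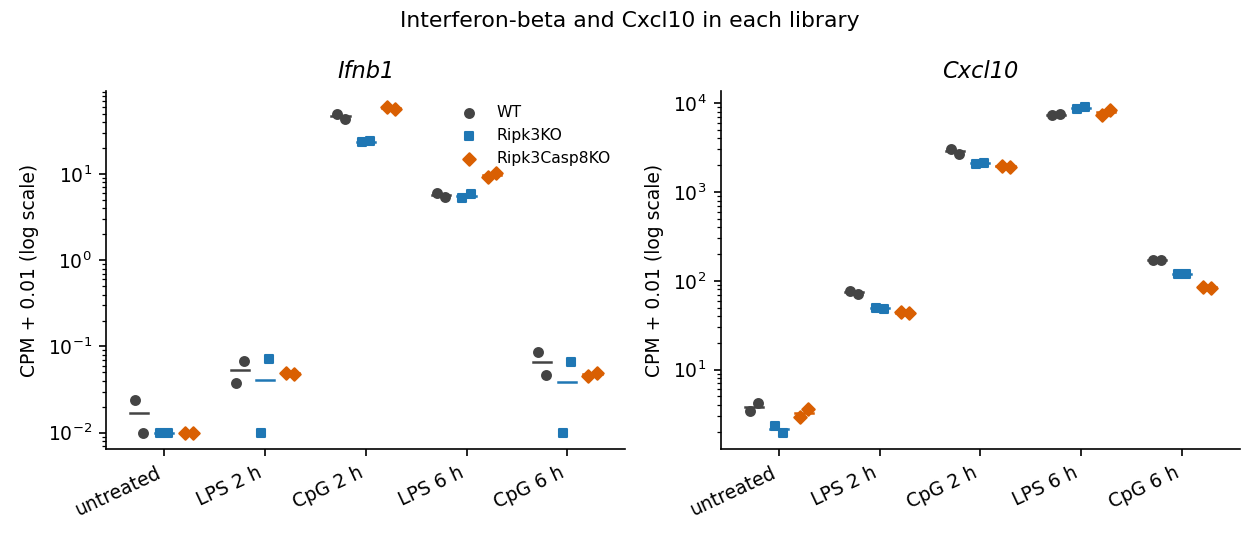
Ifnb1 and Cxcl10 in CPM plus 0.01 on log axes, by condition and genotype, with a point for each library. In every genotype the libraries labelled CpG 2 h lie above those labelled LPS 2 h, and the LPS libraries lie above the CpG libraries at 6 h.

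Without stimulation, loss of Casp8 on the Ripk3-null background went with higher interferon-stimulated genes and lower cell cycle genes. Of 50 interferon-stimulated genes 42 were higher and none lower (adjusted over the list alone, 44 and 0), by a median of 0.69 (camera adjusted p = 2.32e-71). The reference, Ripk3KO, had these genes lower than WT by a median of -0.69. Set against WT, in a comparison not fixed beforehand, Ripk3Casp8KO had 9 higher and 3 lower (adjusted over the list alone, 9 and 5, median -0.01, camera adjusted p = 0.809). Those higher than in Ripk3KO included Zbp1, a sensor of nucleic acids (1.72, SE 0.12, adjusted p = 5.91e-09), and Ifi44 (2.72, SE 0.33, adjusted p = 9.86e-06). Large rises were those of Saa3, an acute-phase protein, at 16.8 ± 1.42 against 0.21 ± 0.00983 CPM (6.30, SE 0.81, adjusted p = 3.37e-05), the chemokine Ccl5 at 6.28 ± 0.473 against 0.207 ± 0.185 (4.88, SE 0.26, adjusted p = 1.66e-10), and complement C3 at 136 ± 2.93 against 12.6 ± 2.96 (3.43, SE 0.13, adjusted p = 5.86e-13). Acod1, which makes itaconate, rose by 2.40 (SE 0.10, adjusted p = 7.61e-12). Of 27 NF-kB feedback genes 14 were higher (adjusted over the list alone, 16 higher and 1 lower, median 0.21, camera adjusted p = 1.68e-12), such as Traf1 (1.29, SE 0.09, adjusted p = 3.85e-09) and Tnfaip3, which encodes A20 (0.84, SE 0.07, adjusted p = 3.17e-08).

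Antigen presentation and macrophage identity genes were also higher in untreated Ripk3Casp8KO than in Ripk3KO cells. The reference, Ripk3KO, had antigen presentation genes lower than WT, as given below, while identity genes were also higher in Ripk3Casp8KO than in WT. Against Ripk3KO, 11 of 19 antigen presentation genes rose and 1 fell (adjusted over the list alone, 12 and 1, median 0.46, camera adjusted p = 2.46e-14), with H2-K1 up by 0.99 (SE 0.07, adjusted p = 5.91e-09). Of 19 identity genes 12 rose (adjusted over the list alone, 13, median 0.31, camera adjusted p = 5.28e-24), with the complement gene C1qa up by 0.78 (SE 0.06, adjusted p = 1.27e-08). Of 30 cell cycle genes 17 fell (adjusted over the list alone, 20, median -0.43, camera adjusted p = 8.9e-25), such as the cyclin gene Ccna2 (-0.66, SE 0.08, adjusted p = 1.01e-05). Of 16 unfolded protein and amino acid response genes 11 fell and 1 rose (adjusted over the list alone, 13 and 1, median -0.27, camera adjusted p = 1.68e-12), with Asns, asparagine synthetase, at 36.3 ± 0.778 against 82.8 ± 0.525 CPM (-1.19, SE 0.08, adjusted p = 5.91e-09). Phgdh, the first enzyme of serine synthesis, fell by 1.44 on the log2 scale (SE 0.12, adjusted p = 5.43e-08). NRF2 targets fell in 7 of 14 (adjusted over the list alone, 8, camera adjusted p = 7.15e-07). Glycolysis and hypoxia genes fell in 12 of 24 with 1 higher (adjusted over the list alone, 13 and 2, camera adjusted p = 1.15e-07). The cytokine list had 2 higher and 1 lower of 27 (adjusted over the list alone, the same, camera adjusted p = 0.79), where 11 of the 27 had at most 3 counts in a group.

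Markers of other cell types gave camera adjusted p-values above the threshold in untreated cells, 0.877 for 8 neutrophil, 0.571 for 10 dendritic, 0.942 for 10 lymphocyte, 0.942 for 4 mast cell and basophil, 0.0833 for 8 osteoclast and 0.942 for 2 erythroid genes. The fibroblast list was the exception, with 3 of 10 higher (adjusted over the list alone, 5, median 1.35, camera adjusted p = 0.00401), and this call was lost with an estimated correlation (adjusted p = 0.0513). Sex-linked and dissociation stress genes gave 0.61 and 0.942. In all, 1553 genes were called, 840 higher and 713 lower, of which 121 and 36 by at least 2-fold, and the share of higher calls went from 54.1% to 43.9% with library size as the only scaling. The count was 779 and 947 without Ripk3KO replicates 1 and 2, and 811 and 1006 without Ripk3Casp8KO replicates 1 and 2.

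In the libraries labelled LPS 2 h, interferon-stimulated genes were higher and cytokine and cell cycle genes lower after loss of Casp8. Of 50 interferon-stimulated genes 45 rose (adjusted over the list alone, 48 higher and 1 lower), by a median of 0.92 (camera adjusted p = 1.26e-110). The reference, Ripk3KO, had these genes lower than WT in this condition. Set against WT, Ripk3Casp8KO had a smaller rise, whose set test lost its call with an estimated correlation. Against Ripk3KO, Irf7, the transcription factor of the type I interferon response, rose by 2.21 (SE 0.13, adjusted p = 5.67e-10) and Zbp1 by 2.22 (SE 0.11, adjusted p = 7.81e-11). Of 27 cytokines 11 fell and 1 rose (adjusted over the list alone, 14 and 2, median -0.32, camera adjusted p = 4e-07). Il12b was at 116 ± 1.73 against 276 ± 5.65 CPM (-1.25, SE 0.08, adjusted p = 6.32e-10), Tnf at 1550 ± 8.62 against 1940 ± 29.3 (-0.32, SE 0.05, adjusted p = 9.4e-05). Csf2 fell by 1.44 on the log2 scale (SE 0.14, adjusted p = 1.17e-06). Il6 (-1.08, SE 0.21, adjusted p = 0.00173) and Il1b (-0.69, SE 0.14, adjusted p = 0.00165) were also lower. Il12b, Il6 and Il1b lost their calls when the authors' log2 table was tested with limma (-1.26, -1.09 and -0.70), and Il6 also with limma-voom (-1.08).

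Of 30 cell cycle genes 23 fell in the libraries labelled LPS 2 h (adjusted over the list alone, 26, median -0.58, camera adjusted p = 9.65e-38), with the proliferation marker Mki67 at -0.79 (SE 0.05, adjusted p = 2.94e-09). Unfolded protein and amino acid response genes fell in 14 of 16, also adjusted over the list alone (median -0.28, camera adjusted p = 4.27e-22), with the stress pseudokinase Trib3 at -1.74 (SE 0.14, adjusted p = 2.04e-08). Identity genes rose in 12 of 19 (adjusted over the list alone, 14, camera adjusted p = 5.41e-16). Outside the lists, Cd55, which encodes a complement inhibitor, rose from 2.36 ± 0.717 to 17.1 ± 1.69 CPM (2.87, SE 0.23, adjusted p = 2.63e-08). Camk2d, a calmodulin-dependent kinase gene, fell from 183 ± 2.12 to 54.6 ± 1.74 (-1.75, SE 0.09, adjusted p = 1.29e-10). The test called 1930 genes, 1069 higher and 861 lower, against 907 higher and 1069 lower under library size alone, where the share of higher calls went from 55.4% to 45.9%. The count was 1078 without Ripk3KO replicate 1, 1113 without Ripk3Casp8KO replicate 1, and 1037 with only the libraries of the compared groups. Ripk3KO replicate 1 stood apart in this group, with 16597 genes detected against 17493 in replicate 2.

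In the libraries labelled CpG 2 h, 16 of 27 cytokines were lower after loss of Casp8 and 1 was higher, with the same counts adjusted over the list alone (median -0.64, camera adjusted p = 5.24e-22). Il12b was at 134 ± 11.9 against 635 ± 17.5 CPM (-2.25, SE 0.08, adjusted p = 1.37e-13), Il1b at 96.6 ± 4.24 against 316 ± 9.94 (-1.71, SE 0.14, adjusted p = 3.14e-08). Il6 was at 21.3 ± 0.766 against 48.8 ± 1.16 (-1.20, SE 0.12, adjusted p = 9.69e-07), and Csf2 at 2.36 ± 0.091 against 12.4 ± 1.33 (-2.38, SE 0.15, adjusted p = 9.95e-09). Il10 was lower too (-0.56, SE 0.10, adjusted p = 0.000629). Il23a, the p19 subunit of IL-23, was at 0.123 ± 0.0962 against 1.09 ± 0.0296 CPM (-3.28, SE 0.68, adjusted p = 0.0027), a call lost with DESeq2 (-3.30) and without Ripk3Casp8KO replicate 2 (-2.49). Of 50 interferon-stimulated genes 40 rose and none fell, over all genes and adjusted over the list alone (median 0.60, camera adjusted p = 2.19e-61), with Ifit3, an antiviral protein, at 1.51 (SE 0.09, adjusted p = 6.16e-10). The reference, Ripk3KO, had these genes lower than WT in this condition. Set against WT, Ripk3Casp8KO had more of them lower than higher without a set test call, as given under other observations. Ifnb1 itself was at 58.2 ± 2.11 CPM in Ripk3Casp8KO against 23.8 ± 0.337 in Ripk3KO (1.29, SE 0.14, adjusted p = 3.35e-06), a call lost in the authors' log2 table with limma (1.29). WT lay between these levels.

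NF-kB feedback genes went down in the libraries labelled CpG 2 h, 10 of 27 against 3 higher (adjusted over the list alone, 12 and 4, median -0.15, camera adjusted p = 4.59e-06). Of 22 chemokines 9 fell and 4 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00353, or adjusted p = 0.0704 with an estimated correlation). Ptgs2, the gene of cyclooxygenase-2, fell by 1.34 on the log2 scale (SE 0.12, adjusted p = 1.34e-07) and Ccl2, a monocyte chemokine, by 0.76 (SE 0.05, adjusted p = 3.32e-09). Cell cycle genes fell in 25 of 30 (adjusted over the list alone, 28, median -0.57, camera adjusted p = 1.09e-32). Unfolded protein and amino acid response genes fell in 13 of 16 (adjusted over the list alone, 13 lower and 1 higher, camera adjusted p = 3.31e-22), with Trib3 at -2.05 (SE 0.14, adjusted p = 3.46e-09). Among immediate early genes 9 of 26 fell and 2 rose (adjusted over the list alone, 10 and 2, camera adjusted p = 8.23e-06), the phosphatase gene Dusp1 by 1.05 on the log2 scale (SE 0.09, adjusted p = 2.92e-08), while Fos rose by 1.94 (SE 0.23, adjusted p = 4.03e-06). Of 1830 genes called 899 were higher and 931 lower. The count was 1182 and 1219 without Ripk3KO replicates 1 and 2, and 1192 and 1211 without Ripk3Casp8KO replicates 1 and 2.

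After LPS for 6 h, loss of Casp8 went with lower cytokine, chemokine, NF-kB feedback and sterol synthesis genes. Of 27 cytokines 19 fell and 3 rose, with the same counts adjusted over the list alone (median -0.94, camera adjusted p = 2.12e-43). Il12b was at 362 ± 12.3 against 2060 ± 102 CPM, 5.68-fold lower (-2.51, SE 0.08, adjusted p = 1.13e-14). Il12a, the p35 subunit of IL-12, was at 1.23 ± 0.122 against 16.6 ± 1.71 (-3.75, SE 0.33, adjusted p = 3.06e-07). In all, 4 of the 5 IL-12 family genes fell, over all genes and adjusted over the list alone (median -1.75, camera adjusted p = 1.93e-35). Il1b (chromosome 2, 129364570 to 129371139) was at 774 ± 21.9 against 6010 ± 48.8 CPM, 7.77-fold lower (-2.96, SE 0.14, adjusted p = 9.47e-12). Il6 (chromosome 5, 30013114 to 30019981) was at 589 ± 28.6 against 2340 ± 347 (-1.99, SE 0.11, adjusted p = 2.16e-10). Tnf was at 2180 ± 17.5 against 7190 ± 442 (-1.72, SE 0.05, adjusted p = 5.67e-15), with WT between these levels, and Csf2 at 2.49 ± 0.137 against 42.4 ± 8.52 (-4.09, SE 0.16, adjusted p = 8.92e-12). Il10 went the other way, at 185 ± 3.46 against 86.3 ± 4.56 CPM (1.10, SE 0.09, adjusted p = 1.56e-08). Rel was at 187 ± 36.7 against 183 ± 12.5 CPM (0.03, SE 0.15, adjusted p = 0.934).

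Chemokines fell in 11 of 22 after LPS for 6 h and 2 rose (adjusted over the list alone, 14 and 3, median -0.35, camera adjusted p = 3.75e-21), the neutrophil chemokine Cxcl1 from 446 ± 80.3 to 63.4 ± 5.3 CPM (-2.81, SE 0.11, adjusted p = 4.71e-13). WT lay between these levels of Cxcl1, so part of this change was a rise in Ripk3KO over WT. NF-kB feedback genes fell in 15 of 27 (adjusted over the list alone, 18 lower and 1 higher, median -0.29, camera adjusted p = 1.78e-13), with Nfkb2 at -0.83 (SE 0.05, adjusted p = 2.31e-10). Sterol genes were higher in Ripk3KO than in WT in this condition, as given below. From Ripk3KO to Ripk3Casp8KO 16 of 24 sterol genes fell (adjusted over the list alone, 17, median -0.46, camera adjusted p = 1.06e-15), with Hmgcs1, a synthase of the mevalonate pathway, at -1.18 (SE 0.07, adjusted p = 1.11e-10). Of 14 NRF2 targets 8 fell (adjusted over the list alone, 10, median -0.48, camera adjusted p = 1.68e-11), with Slc7a11 at -2.26 (SE 0.11, adjusted p = 9.36e-12). Unfolded protein and amino acid response genes fell in 11 of 16 with 1 higher (adjusted over the list alone, 13 and 2, median -0.39, camera adjusted p = 2.79e-08). Identity genes rose in 12 of 19 with 1 lower (adjusted over the list alone, 13 and 1, camera adjusted p = 7.79e-12).

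Interferon-stimulated genes changed less uniformly after LPS for 6 h, with 15 of 50 higher and 1 lower (adjusted over the list alone, 19 and 2, median 0.12). The camera call (adjusted p = 0.000408) was lost with an estimated correlation (adjusted p = 0.54). Ifnb1 was at 9.74 ± 0.662 against 5.6 ± 0.355 CPM (0.80, SE 0.16, adjusted p = 0.00185), a call lost in the authors' log2 table with limma (0.82). The cell cycle list had 7 higher and 4 lower of 30 (adjusted over the list alone, 9 and 4, camera adjusted p = 0.974), with Mki67 lower (-1.30, SE 0.06, adjusted p = 1.82e-12) and the cyclin gene Ccnd1 higher (1.02, SE 0.09, adjusted p = 6.15e-08). The test called 2588 genes, 1324 higher and 1264 lower, and the share of higher calls went from 51.2% to 61.8% under library size alone. With only the libraries of the compared groups 1007 genes were called.

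**Figure D3:**
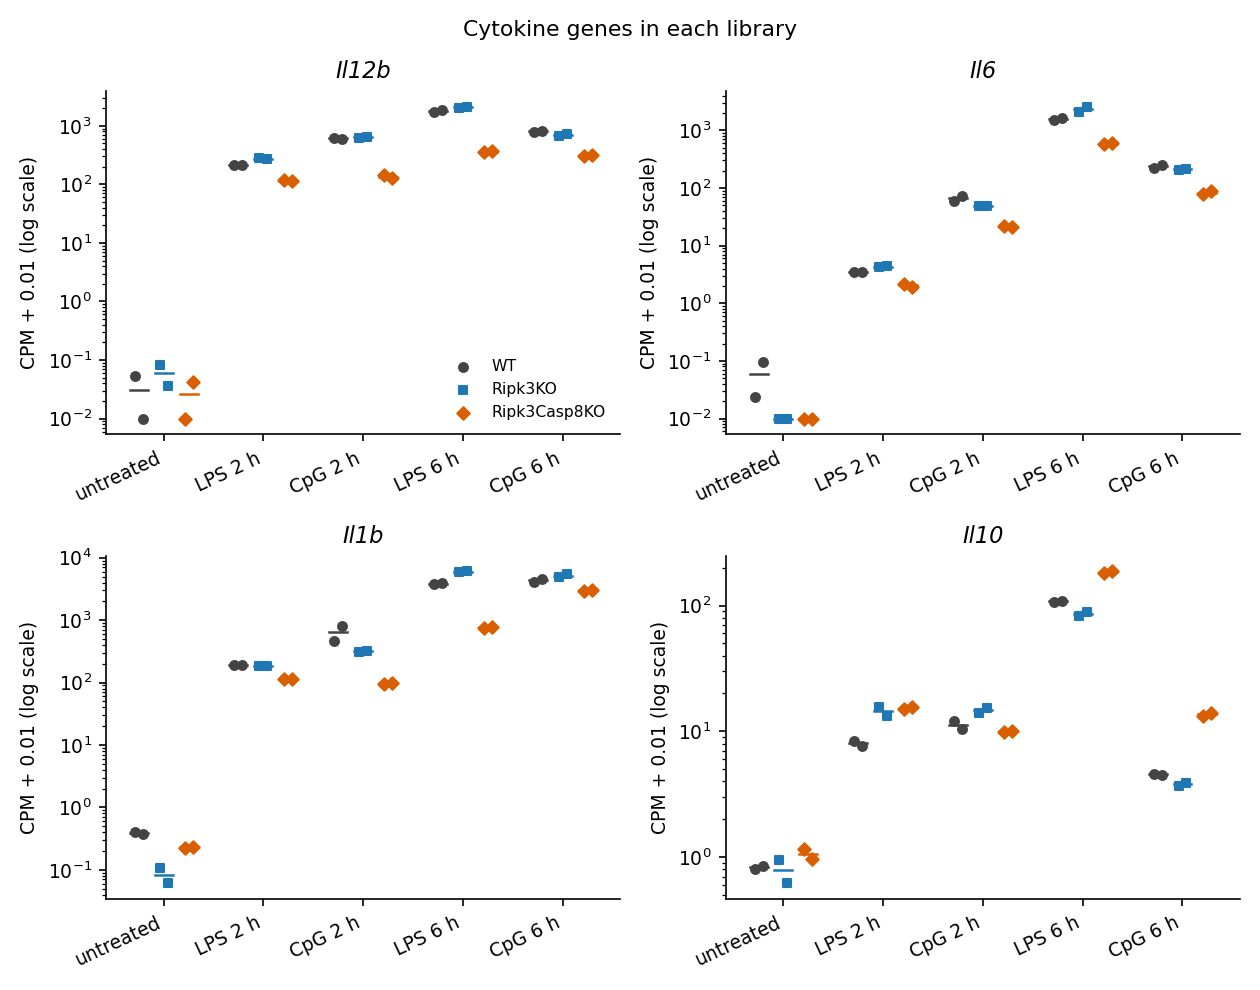
Levels of Il12b, Il6, Il1b and Il10 in CPM plus 0.01 on log axes, by condition and genotype, with a point for each library. After LPS for 6 h Il12b lies near 362 CPM in Ripk3Casp8KO and 2060 in Ripk3KO.

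After CpG for 6 h, the libraries labelled Ripk3Casp8KO had lower cytokine, sterol and cell cycle genes and higher identity genes than those labelled Ripk3KO. Of 27 cytokines 11 fell and 1 rose (adjusted over the list alone, 12 and 2, median -0.39, camera adjusted p = 4.09e-11). Il12b was at 312 ± 5 against 707 ± 36.9 CPM (-1.18, SE 0.07, adjusted p = 1.67e-09), a call lost in the authors' log2 table with limma (-1.19). Il6 was at 83.2 ± 7.24 against 210 ± 3.76 (-1.33, SE 0.11, adjusted p = 1.45e-07), Il1b at 2990 ± 98.6 against 5190 ± 297 (-0.80, SE 0.13, adjusted p = 0.000393). Tnf was at 1770 ± 14.4 against 2520 ± 233 (-0.50, SE 0.05, adjusted p = 5.83e-07). Il10 was higher, at 13.6 ± 0.683 against 3.77 ± 0.151 (1.85, SE 0.11, adjusted p = 1.24e-09). Rel was at 74.9 ± 3.35 against 104 ± 40 CPM (-0.47, SE 0.16, adjusted p = 0.0618) and was called without Ripk3KO replicate 2 (-0.82) and by DESeq2 (-0.48). Chemokines fell in 9 of 22 with 1 higher (adjusted over the list alone, 12 and 2, median -0.37, camera adjusted p = 9.72e-11), with Ccl22, a chemokine for T cells, at -1.26 (SE 0.15, adjusted p = 5.78e-06).

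Of 24 sterol genes 14 fell after CpG for 6 h (adjusted over the list alone, 17, median -0.42, camera adjusted p = 7.65e-18), with Fdft1, squalene synthase, which lies within 10 Mb of Ripk3, at -0.53 (SE 0.07, adjusted p = 5.31e-05). Of 30 cell cycle genes 18 fell and 1 rose (adjusted over the list alone, 19 and 3, median -0.53, camera adjusted p = 3.91e-25), with Mki67 at -0.90 (SE 0.05, adjusted p = 1.24e-09). Identity genes rose in 14 of 19 (adjusted over the list alone, 16, median 0.47, camera adjusted p = 3.94e-28), C1qa by 0.93 (SE 0.06, adjusted p = 1.67e-09) and the transcription factor gene Maf by 0.81 (SE 0.05, adjusted p = 1.24e-09). NRF2 targets fell in 7 of 14 (adjusted over the list alone, 8, camera adjusted p = 6.21e-10). The interferon list had 10 higher and 7 lower of 50 (adjusted over the list alone, 10 and 8, median -0.01, camera adjusted p = 0.688), with the guanylate-binding protein gene Gbp5 lower (-0.97, SE 0.11, adjusted p = 2.89e-06). Cxcl10 was also lower, at 84.9 ± 1.65 against 118 ± 1.25 CPM (-0.48, SE 0.08, adjusted p = 0.00021). Cd55 rose 8.92-fold, from 5.59 ± 1.26 to 49.5 ± 1.98 CPM (3.16, SE 0.22, adjusted p = 5.56e-09). Mmp12, macrophage elastase, fell (-1.54, SE 0.08, adjusted p = 2.01e-10). The test called 1492 genes, 763 higher and 729 lower. With only the libraries of the compared groups 385 were called, without Ripk3Casp8KO replicate 1 and replicate 2 there were 947 and 837, and without Ripk3KO replicate 2 there were 1792.

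Averaged over the 4 stimulated conditions, cytokines fell in 17 of 27 with 1 higher (adjusted over the list alone, 20 and 2, median -0.66, camera adjusted p = 2.46e-30). All 5 IL-12 family genes fell, also adjusted over the list alone (camera adjusted p = 2.62e-23), Il12b by 1.79 on the log2 scale (SE 0.04, adjusted p = 1.23e-17). Csf2 changed by -2.29 (SE 0.07, adjusted p = 2.23e-13), Camk2d by -1.80 (SE 0.05, adjusted p = 2.66e-16), Irs2, an insulin signalling adaptor, by -1.76 (SE 0.05, adjusted p = 2.47e-15), Cd55 by 2.90 (SE 0.11, adjusted p = 1.46e-13) and Il10 by 0.62 (SE 0.05, adjusted p = 6.78e-09). The direction of Il10 differed between these conditions, as it was called lower in the libraries labelled CpG 2 h and higher after either agonist at 6 h. Rel changed by -0.28 (SE 0.08, adjusted p = 0.00944), a call lost with only the libraries of the compared groups (-0.28) and without the 2 h libraries (-0.22). Interferon-stimulated genes rose in 43 of 50 with 3 lower (adjusted over the list alone, 43 and 4, median 0.44, camera adjusted p = 1.52e-43). This average rests mainly on the 2 h libraries. At LPS 6 h the set test call was lost with an estimated correlation, and at CpG 6 h the set test made no call, as given above. The reference, Ripk3KO, had these genes lower than WT in the stimulated conditions other than LPS 6 h. Set against WT, their direction in Ripk3Casp8KO differed between conditions, as given under other observations. Against Ripk3KO, cell cycle genes fell in 24 of 30 with 1 higher, the same counts as adjusted over the list alone (median -0.39, camera adjusted p = 1.42e-23). The mean contrast called 3915 genes, 2039 higher and 1876 lower, against 2393 without the 2 h libraries. Over the 5 single conditions 160 genes were called higher in each, 95 lower in each, and 319 were called in opposite directions in different conditions.

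**Figure D4:**
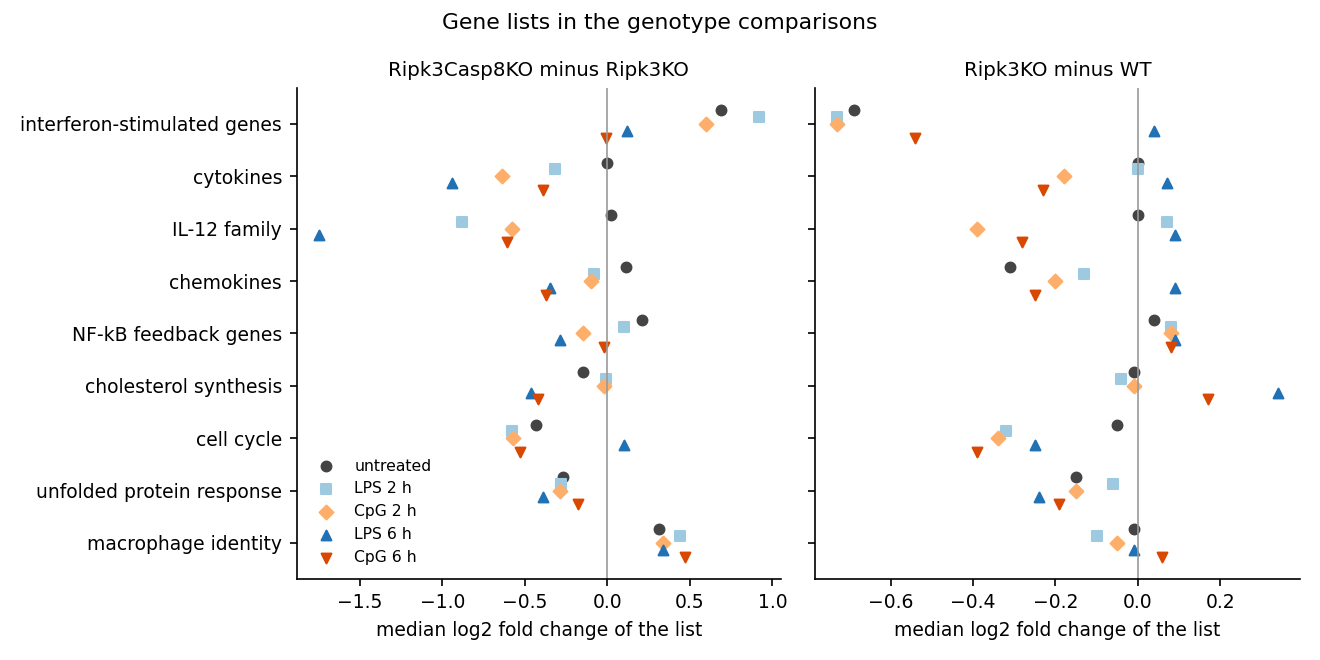
Median log2 fold change of each gene list for the loss of Casp8 and for the loss of Ripk3, by condition, for 9 lists, with a point for each list and condition and panels whose x scales differ. The cytokine medians for Casp8 loss run from 0.00 untreated to -0.94 after LPS for 6 h.

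Loss of Ripk3 with Casp8 intact, Ripk3KO against WT, went with lower interferon-stimulated and antigen presentation genes. In untreated cells 46 of 50 interferon-stimulated genes fell (adjusted over the list alone, 48), by a median of -0.69 (camera adjusted p = 1.9e-143). Of 19 antigen presentation genes 9 fell (adjusted over the list alone, 14, median -0.42, camera adjusted p = 1.55e-27). Zbp1 changed by -1.37 (SE 0.12, adjusted p = 1.78e-07) and H2-Aa, an MHC class II gene, by -1.11 (SE 0.10, adjusted p = 1.86e-07). The interferon counts were 43 of 50 lower in the libraries labelled LPS 2 h (adjusted over the list alone, 47), 46 in those labelled CpG 2 h (47 adjusted over the list alone) and 43 at CpG 6 h (48 lower and 1 higher adjusted over the list alone), with medians of -0.73, -0.73 and -0.54 (camera adjusted p = 1.16e-86, 5.37e-125 and 4.43e-92). At LPS 6 h 3 rose and 1 fell (adjusted over the list alone, 4 and 1, median 0.04, camera adjusted p = 0.174). Irf7 changed by -1.50 in the libraries labelled LPS 2 h (SE 0.13, adjusted p = 2.36e-07), and Iigp1 by -1.79 in those labelled CpG 2 h (SE 0.14, adjusted p = 3.25e-08). In the latter Ifnb1 was at 23.8 ± 0.337 against 47.3 ± 4.51 CPM (-0.99, SE 0.14, adjusted p = 0.000137, a call lost in the authors' log2 table with limma, -0.98). Antigen presentation genes fell in 12, 9, 4 and 6 of 19 in the libraries labelled LPS 2 h, CpG 2 h, LPS 6 h and CpG 6 h (adjusted over the list alone, 14, 11, 4 and 9, with 1 higher at CpG 6 h, camera adjusted p = 1.7e-17, 5.18e-18, 0.00213 and 1.57e-09, and for LPS 6 h adjusted p = 0.209 with an estimated correlation).

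Over the 5 conditions of the Ripk3 comparison 2560 genes were called in at least 1, of which 47 were called higher in each, 48 lower in each, and 73 in opposite directions in different conditions. The largest changes named for the mean of the stimulated conditions had to keep their direction in all 4 to be named. The genes that were always named and the list members did not. Adra1a, an adrenergic receptor gene, was at 28.2 ± 1.59 against 7.61 ± 0.218 CPM in untreated cells (1.89, SE 0.08, adjusted p = 1.21e-11) and changed by 1.66 on the mean of the stimulated conditions (SE 0.04, adjusted p = 6.26e-16). Slc7a7, an amino acid transporter gene, changed by 1.37 (SE 0.05, adjusted p = 1.92e-14). Both are on the chromosome of Ripk3, Slc7a7 within 10 Mb of it (chromosome 14, 54369442 to 54417780) and Adra1a just beyond (66635251 to 66771168). Pira2, one of a family of paired receptors, was at 18.6 ± 0.155 against 91 ± 1.11 CPM (-2.29, SE 0.10, adjusted p = 8.61e-12) and changed by -2.55 on the mean (SE 0.05, adjusted p = 3.8e-18). The growth factor gene Gdf3 was at 2.83 ± 0.0158 against 20.8 ± 0.384 (-2.88, SE 0.15, adjusted p = 1.61e-10). Pira2, like the MHC gene H2-K1, belongs to a family of similar genes, whose reads the counting could split. Il12b was higher in the libraries labelled LPS 2 h, at 276 ± 5.65 against 217 ± 1.9 CPM (0.35, SE 0.07, adjusted p = 0.00472). This call was lost in the authors' log2 table with limma (0.34), without WT replicate 1 (0.34) and without Ripk3KO replicate 1 (0.33). Il12b did not pass the test in the libraries labelled CpG 2 h or at 6 h, with changes of 0.06, 0.19 and -0.20 (adjusted p = 0.765, 0.133 and 0.128 for CpG 2 h, LPS 6 h and CpG 6 h). At LPS 6 h Tnf was at 7190 ± 442 against 5320 ± 26.7 CPM (0.43, SE 0.05, adjusted p = 8.5e-06) and Cxcl1 at 446 ± 80.3 against 133 ± 6.2 (1.75, SE 0.10, adjusted p = 1.25e-09). Of 24 sterol genes 12 rose (adjusted over the list alone, 15, median 0.34, camera adjusted p = 1.46e-12).

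Cell cycle genes were lower in the libraries labelled Ripk3KO than in WT in the stimulated conditions other than LPS 6 h by the set test with an estimated correlation. In the libraries labelled LPS 2 h 17 of 30 fell and 2 rose (camera adjusted p = 3.04e-14), in those labelled CpG 2 h 15 fell and 3 rose (camera adjusted p = 2.78e-10). At CpG 6 h 21 fell (camera adjusted p = 3.47e-27). The falls were 17, 18 and 24 adjusted over the list alone. At LPS 6 h 9 fell and 1 rose (adjusted over the list alone, 14 and 2, camera adjusted p = 1.25e-05), a call lost with an estimated correlation (adjusted p = 0.0517). Glycolysis and hypoxia genes rose in 12 and 13 of 24 after LPS and CpG for 6 h with 1 lower in each (adjusted over the list alone, 15 and 20 with 1 lower, camera adjusted p = 5.49e-08 and 7.29e-15). Bnip3, a hypoxia-induced mitophagy gene, rose by 0.72 and 0.89 (SE 0.12 and 0.11, adjusted p = 0.000612 and 3.67e-05). The tests called 382 genes untreated (131 higher), and 1192 and 951 in the libraries labelled LPS 2 h and CpG 2 h (505 and 331 higher). They called 987 and 921 after LPS and CpG for 6 h (473 and 349 higher), and 2676 on the mean (1164 higher). Under library size alone the share of higher calls went from 47.9% to 27.5% at LPS 6 h and from 43.5% to 36.1% on the mean. With no expression filter it went from 42.4% to 25.8% in the libraries labelled LPS 2 h, with 266 higher and 764 lower. With only the libraries of the compared groups the 4 stimulated counts were 602, 593, 125 and 113, and without the 2 h libraries the mean count was 1143. The Casp8 comparisons share the Ripk3KO libraries with these, so the chance values of those libraries enter both sets of changes with opposite signs.

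The Ripk3 counts fell by over 1.5 times when some single libraries were left out. Untreated, 224 genes were called without Ripk3KO replicate 1, 245 without Ripk3KO replicate 2 and 248 without WT replicate 2. In the libraries labelled LPS 2 h there were 471 without Ripk3KO replicate 1, 489 without WT replicate 1 and 542 without WT replicate 2, and in those labelled CpG 2 h 542 without Ripk3KO replicate 1, 566 without Ripk3KO replicate 2 and 604 without WT replicate 2. With LPS for 6 h there were 514 and 611 without WT replicates 1 and 2 and 568 without Ripk3KO replicate 2, and after CpG for 6 h 607 and 479 without WT replicates 1 and 2.

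The response to stimulation was compared between Ripk3Casp8KO and Ripk3KO as an interaction. Genotypes and conditions here are those of the labels. NF-kB feedback genes rose less with stimulation in Ripk3Casp8KO in all 4 conditions, with 9, 12, 17 and 8 of 27 lower over all genes for LPS 2 h, CpG 2 h, LPS 6 h and CpG 6 h and 1 higher at CpG 6 h (adjusted over the list alone, 12, 16, 18 and 10 lower and 1 higher at CpG 6 h, camera adjusted p = 5.91e-17, 2.26e-40, 2.41e-33 and 1.66e-10). Tnfaip3 differed by -1.54 (SE 0.09, adjusted p = 5.1e-10) and Traf1 by -1.73 (SE 0.10, adjusted p = 6.02e-10) at LPS 6 h. Both, like other genes of this list, were already higher in untreated Ripk3Casp8KO than in Ripk3KO cells, so part of these interactions is the untreated difference. Lower stimulated levels of the list are given above only for the libraries labelled CpG 2 h and for LPS 6 h. Genes that were high in untreated Ripk3Casp8KO cells gave large negative interactions, such as Ccl5 at -4.81, -4.95, -4.97 and -5.12 (adjusted p = 8.13e-09, 1.73e-09, 4.09e-10 and 8.44e-10) and C3 at -2.17 in the libraries labelled LPS 2 h and -2.71 at CpG 6 h (SE 0.16 each, adjusted p = 1.88e-07 and 3.38e-09). Interferon-stimulated genes rose less at 6 h, with 33 of 50 lower after LPS (adjusted over the list alone, 37, median -0.60, camera adjusted p = 3.04e-31) and 33 after CpG (adjusted over the list alone, 46, median -0.67, camera adjusted p = 1.26e-82). These genes were already higher in untreated Ripk3Casp8KO than in Ripk3KO cells, and the medians of the 2 groups lay close at 6 h. The interactions of this list therefore largely carry the untreated difference. Of the 27 cytokines 11 had at most 3 counts in an untreated group, so no set test of their interactions is given. Tnf differed by -1.62 at LPS 6 h (SE 0.07, adjusted p = 2.52e-11). Il12b, Il6, Il12a and Ifnb1 were near 0 counts in untreated cells, so no interaction is given for them.

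The interactions called 121 genes (38 higher), 265 (76 higher), 1375 (660 higher) and 432 (171 higher) in the order LPS 2 h, CpG 2 h, LPS 6 h and CpG 6 h, of which 0, 6, 19 and 7 had at most 3 counts in a group. Under library size alone the share of higher calls went from 28.7% to 38.7% at CpG 2 h, from 48% to 64.9% at LPS 6 h and from 39.6% to 49.5% at CpG 6 h (225 higher and 230 lower). With only the libraries of the compared groups the counts for LPS 2 h, LPS 6 h and CpG 6 h were 72, 695 and 127 (13.9% higher at LPS 2 h and 22% at CpG 6 h), and DESeq2 gave 251, 408 and 674 for LPS 2 h, CpG 2 h and CpG 6 h. The CpG 6 h count was 284 without the 2 h libraries. For LPS 2 h the count was 72 and 78 without untreated Ripk3KO replicates 1 and 2, 80 without Ripk3KO replicate 1 and 76 without Ripk3Casp8KO replicate 1 of the stimulated libraries. For CpG 2 h it was 170 and 165 without untreated Ripk3KO replicates 1 and 2, and 174 without untreated Ripk3Casp8KO replicate 2 or stimulated Ripk3Casp8KO replicate 1. For CpG 6 h it was 246 without untreated Ripk3KO replicate 1, 251 without untreated Ripk3Casp8KO replicate 1 and 278 without stimulated Ripk3Casp8KO replicate 2.

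The effect of Casp8 loss on cytokines also differed between the agonists at 6 h. It was lower after LPS than after CpG for 12 of 27 cytokines and higher for 1 (adjusted over the list alone, 15 and 1, median -0.69, camera adjusted p = 3.89e-23). It was lower for 10 of 22 chemokines with 1 higher (adjusted over the list alone, 11 and 4, camera adjusted p = 3.46e-09). The difference of the effects was -3.14 for Il12a (SE 0.46, adjusted p = 0.000296), -2.86 for Csf2 (SE 0.21, adjusted p = 1.4e-07), -2.16 for Il1b (SE 0.19, adjusted p = 2.64e-07) and -1.22 for Tnf (SE 0.07, adjusted p = 2.51e-09). It was -1.33 for Il12b (SE 0.10, adjusted p = 6.99e-08), whose call was lost in the authors' log2 table with limma (-1.30). Cell cycle genes went the other way, with 15 of 30 higher and 1 lower (adjusted over the list alone, 17 and 2, median 0.41, camera adjusted p = 1.03e-12). The 6 h test called 1162 genes (583 higher), and under library size alone the share of higher calls went from 50.2% to 61.2%. It called 259 with only the libraries of the compared groups and 728 without CpG 6 h Ripk3Casp8KO replicate 2. Between the libraries labelled LPS 2 h and CpG 2 h 41 genes were called, all higher, among them Dusp1 (1.22, SE 0.12, adjusted p = 7.99e-05) and Irf7 (1.37, SE 0.18, adjusted p = 0.000644). The count was 18 under library size alone, 13 with only the libraries of the compared groups, 126 with DESeq2 (101 higher and 25 lower) and 23 in the authors' log2 table with limma. Without LPS 2 h Ripk3Casp8KO replicates 1 and 2 the count was 9 and 21, without LPS 2 h Ripk3KO replicate 1 it was 10, and without CpG 2 h Ripk3KO replicates 1 and 2 or Ripk3Casp8KO replicates 1 and 2 it was 16, 14, 11 and 16.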

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

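The test of the Ripk3 change at CpG 6 h against the other conditions and the test of LPS contaminating the CpG were chosen only after the result was seen.

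The first pattern is the order of the agonists at 2 h. Interferon-stimulated genes were lower in the libraries labelled LPS than in those labelled CpG at 2 h, with medians of -1.93, -1.99 and -1.52 in WT, Ripk3KO and Ripk3Casp8KO over the genes compared at both times, and higher after LPS at 6 h (3.19, 3.62 and 3.97). If the labels had been exchanged at 2 h, genes outside the interferon list would also run opposite at the 2 times, and across 11779 such genes Pearson's r was -0.54, -0.45 and -0.49 (Spearman's rho -0.46, -0.37 and -0.4), where genes are not independent replicates and the highest of the 3 values was -0.45. An exchange of the LPS and CpG labels of all 2 h libraries is therefore a candidate explanation. Only the listed interferon-stimulated genes were left out, so unlisted ones may carry part of this opposition, and the test is not independent of the pattern. LPS contaminating the CpG is argued against as the whole cause only if the 2 h labels are taken as given. With exchanged labels, the libraries labelled LPS 2 h would not show what LPS does. For contamination to be the cause, LPS itself would have to raise the listed interferon-stimulated genes at 2 h. Against untreated cells, their median change was 0.12, -0.01 and 0.26 in the libraries labelled LPS 2 h and 2.20, 2.00 and 1.84 in those labelled CpG 2 h. Ifnb1 had 3, 2 and 2 counts over the group in the libraries labelled LPS 2 h against 2818, 1262 and 3309 in those labelled CpG 2 h, and 3, 2 and 2 after CpG at 6 h against 243, 242 and 388 after LPS. A true difference in timing between the agonists was not excluded.

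The second pattern is Ripk3 at CpG 6 h, where the knockout difference was closer to 0 than in the other conditions by 0.95 (SE 0.13, adjusted p = 0.00108), a test of the condition that had already stood out. Wild-type cells under the knockout labels are argued against, because over 109 genes that separated Ripk3KO from WT in the 4 other conditions the difference at CpG 6 h had a slope of 0.96 (95% interval 0.93 to 1) on their mean there, with 107 of the same sign. Reads of a neighbouring gene counted as Ripk3 remain open, since the median change of 8 genes within 100 kb was -0.22, with Tgm1 at 1.77 and Nynrin at -2.01, which is neither the rise this would need nor within the bound set for its absence. Transcription of the altered locus under CpG may also account for it and was not tested.

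The third pattern is the number of genes called for each genotype. Among 100 splits that exchanged libraries within conditions, the real split for Casp8 was the 1 with as many calls. It had 3790 by limma-voom against 2649 in the highest of the others. For Ripk3 the real split was again the 1, with 2544 against 1473. Splits that mix genotypes widen the spread within groups, and the replicates may be technical. The splits therefore cannot exclude chance differences between mice or cultures. DNA of another strain around the targeted loci stays open. Genes within 10 Mb of Casp8 were 0.72% of the genes called for Casp8 loss (28 of 102 tested) and those within 10 Mb of Ripk3 were 1.76% of the genes called for Ripk3 loss (47 of 176 tested). The share called was 27.5% near Casp8 against 26.1% of other genes. Near Ripk3 it was higher than elsewhere, at 26.7% against 17.8%, a difference that was not tested. The flanks hold too few tested genes to make up over 2.6% and 6.6% of the calls. Their part of the calls therefore decides nothing, and effects on distant genes were not tested. Slc7a7, given above for Ripk3 loss, lies in that flank and Adra1a just beyond it on the same chromosome. Strain-derived DNA elsewhere, separate breeding of the lines and the losses themselves stay open, as the design holds no second line of any genotype.

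The remaining results are differences between effects that passed a test of the difference itself. The effect of Casp8 loss differed from that in untreated cells for 121 genes in the libraries labelled LPS 2 h, 265 in those labelled CpG 2 h, 1375 after LPS for 6 h and 432 after CpG for 6 h, and it differed between LPS and CpG for 41 genes at 2 h and 1162 at 6 h. For Cxcl10 these interactions were -0.78, -0.72, -0.77 and -1.09 (adjusted p = 0.022, 0.0208, 0.00325 and 0.000367), and each lost its call with limma-voom. For Il10 they were -0.99 in the libraries labelled CpG 2 h (adjusted p = 0.0209), lost with limma-voom (-1.02), and 1.42 at CpG 6 h (adjusted p = 0.000848), lost with only the libraries of the compared groups (1.41) and without untreated Ripk3KO replicate 1 (1.07). For Tnf they were -1.62 at LPS 6 h (adjusted p = 2.52e-11) and -0.40 at CpG 6 h (adjusted p = 0.00241), the latter lost with limma-voom (-0.41). For Il1b it was -4.47 at LPS 6 h (adjusted p = 0.00874), lost with limma-voom (-4.45) and without either untreated Ripk3Casp8KO library (-4.50 and -4.45). Between the agonists at 6 h the effects differed by -1.33 for Il12b, -3.14 for Il12a, -0.65 for Il6 (adjusted p = 0.00921, a call lost in 4 alternatives), -2.16 for Il1b, -1.22 for Tnf and -0.75 for Il10 (adjusted p = 0.00189). Between the libraries labelled LPS 2 h and CpG 2 h they differed by 1.00 for Il12b (adjusted p = 8.08e-05) and 1.02 for Il1b (adjusted p = 0.0286, a call lost in 12 alternatives).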

How the results depend on the processing

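The alternatives without the 2 h libraries and without the CpG 6 h libraries were chosen after seeing the data, and the others before. Over 1758 pairs of a named gene and a comparison, no called gene changed sign under any alternative fixed beforehand except Ddit3 in the WT response to LPS at 6 h with library size alone (-0.09, adjusted p = 0.429). Without the 2 h libraries 7 changed sign, 3 for Casp8 loss averaged over conditions, Ripk3 at 0.07, Sesn2 at 0.70 and S100a8 at -0.12, and 4 for Ripk3 loss, Il1b at 0.45, Il10 at -0.30, Gbp2 at 0.03 and Nqo1 at 0.05, where the average then holds 6 h libraries alone. Calls of named genes were lost 4 times with RLE factors, 39 with library size alone, 107 with no filter, 23 with DESeq2, 93 with limma-voom, 121 in the authors' log2 table with limma, 324 with only the libraries of the compared groups, and 1161 times when a library was left out, against 9358 that stayed on their side of the threshold. The replicate block lost 19, testing only the genes of the authors' log2 table lost 2, and excluding the 10 Mb flanks lost 6. Leaving out the 2 h libraries lost 116 and leaving out the CpG 6 h libraries 33. Of 648 list tests 79 lost their call with an estimated correlation and 12 with fry, while 107 gained a call with fry. Direction was compared with fry alone, where no list called by both tests changed direction.

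Counts of called genes stayed within 1.5 times the main count unless given here. With only the libraries of the compared groups the Casp8 counts were 1037, 1007 and 385 in the libraries labelled LPS 2 h and at LPS and CpG 6 h, the Ripk3 counts 602, 593, 125 and 113 in the 4 stimulated conditions, the interaction counts 72, 695 and 127 at LPS 2 h, LPS 6 h and CpG 6 h, and the counts between agonists 13 at 2 h and 259 at 6 h. These fits have fewer residual degrees of freedom. DESeq2 called 251, 408 and 674 genes for the interactions at LPS 2 h, CpG 2 h and CpG 6 h and 126 between agonists at 2 h, where library size alone gave 18 and the authors' log2 table with limma 23, and the cause was not tested. Without the 2 h libraries the averaged counts were 2393 for Casp8 and 1143 for Ripk3, and the CpG 6 h interaction had 284. The labels do not say whether libraries with the same replicate number share a source. With the replicate number as a block the Casp8 counts were 1525, 1900, 1811, 2552 and 1471 for the 5 conditions and 3879 averaged, and no count moved by over 1.5 times.

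When each library was left out in turn, with a lone remaining library assumed to vary like the other groups, the Casp8 counts ranged from 779 to 1006 untreated, 1078 to 1791 and 1182 to 1219 in the libraries labelled LPS 2 h and CpG 2 h, 1816 to 2149 and 837 to 1792 at LPS and CpG 6 h, and 3586 to 4032 averaged. The Ripk3 counts ranged from 224 to 269, 471 to 1066, 542 to 651, 514 to 1106, 479 to 1114 and 2277 to 2963 in the same order. The WT responses ranged from 4699 to 4880, 5910 to 6054, 9131 to 9248 and 7071 to 7152, and the agonist comparisons from 1229 to 1385 at 2 h and 6645 to 6767 at 6 h. The interactions ranged from 72 to 117, 165 to 189, 936 to 1567 and 246 to 609, and the comparisons of effects between agonists from 9 to 38 at 2 h and 728 to 1646 at 6 h. Depth of 20.42 to 64.09 M counts limits genes with few counts, such as Il12a and Il23a.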

Other observations

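The set tests of Ripk3Casp8KO against WT were not among the comparisons fixed beforehand and count as chosen only after the result was seen.

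Toll-like receptor and inflammasome genes were slightly higher in untreated Ripk3Casp8KO than in Ripk3KO cells. Of 33 TLR signalling genes 8 rose and 1 fell (adjusted over the list alone, 10 and 2, median 0.11, camera adjusted p = 0.00212), with the kinase gene Ikbke up by 0.79 (SE 0.10, adjusted p = 1.45e-05) and Tlr1 by 0.59 (SE 0.07, adjusted p = 3.04e-06). Of 19 inflammasome genes 5 rose and 1 fell (adjusted over the list alone, 7 and 1, median 0.27, camera adjusted p = 0.000231), among them Gsdmd, the pore-forming gasdermin D (0.39, SE 0.07, adjusted p = 0.000678), and Casp4, which encodes caspase-11 (0.79, SE 0.15, adjusted p = 0.000961). Of 29 cell death genes 4 rose and 2 fell, 1 of them Casp8 (adjusted over the list alone, 4 and 3, camera adjusted p = 0.552). After LPS for 6 h Tlr9, the CpG receptor, was higher by 1.40 (SE 0.12, adjusted p = 5.43e-08) and Cd14, the LPS co-receptor, lower (-0.86, SE 0.04, adjusted p = 7.87e-12). Of 20 lysosome genes 6 rose in untreated cells, also adjusted over the list alone (median 0.12, camera adjusted p = 0.000308), with the protease gene Ctss up by 0.62 (SE 0.04, adjusted p = 8.45e-09), and 2 of 12 mitochondrially encoded genes fell (median -0.27, camera adjusted p = 0.00251). The lysosome and mitochondrial calls were lost with an estimated correlation (adjusted p = 0.152 and 0.257).

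Set directly against WT, untreated Ripk3Casp8KO cells had 9 of 50 interferon-stimulated genes higher and 3 lower (adjusted over the list alone, 9 and 5, median -0.01, camera adjusted p = 0.809). Those labelled LPS 2 h had 20 higher and 1 lower (adjusted over the list alone, 21 and 1, median 0.18, camera adjusted p = 6.39e-08, or adjusted p = 0.27 with an estimated correlation). Those labelled CpG 2 h had 3 higher and 12 lower (adjusted over the list alone, 5 and 13, median -0.09, camera adjusted p = 0.0785). At LPS 6 h 20 were higher and 3 lower (adjusted over the list alone, 23 and 3, median 0.21, camera adjusted p = 1.7e-06, or adjusted p = 0.303 with an estimated correlation). At CpG 6 h 41 were lower (adjusted over the list alone, 45, median -0.55, camera adjusted p = 1.06e-43). Unfolded protein and amino acid response genes were lower than in WT in all 5 conditions, in 14, 14, 14, 14 and 13 of 16 (camera adjusted p from 2.24e-22 to 5.52e-10), and identity genes were higher in 14, 13, 9, 13 and 14 of 19. These comparisons share libraries with those of the genotypes above, so they are not independent of them.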
